A study of Homo sapiens with 15 samples.

How the data were processed

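RNA was measured by sequencing in 15 libraries of the pancreatic cancer lines Aspc1 and Panc1, taken 48 h after transfection. Per the series design text, libraries were made from total RNA with an RNA integrity number above 8 with a TruSeq kit and read on a HiSeq instrument. Per the same text, reads were mapped to hg19 with TopHat 2.0.4, allowing 4 mismatches and 10 maximum multiple hits. CASAVA 1.8.2, Cufflinks, DESeq2 and DESeq are named in the submitters' processing notes. Whether the kit kept strand, and the settings of Cufflinks, are not given in the sources used here. Reads with several hits can be split between near-identical genes, so the values of gene family members are less certain, and without strand the reads of overlapping genes cannot be assigned.

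The authors deposited a table per library with the FPKM of 25593 gene entries, its interval and a status, per the file headers, and these FPKM values were used as they stand. For each FAM83H-AS1 siRNA and for LINC00673 siRNA2 the authors deposited a comparison table. Per the file headers these tables hold mean signal (normalised mean counts), log2 fold changes and, in the Aspc1 tables, a test score. The Panc1 table also holds a linear fold change as a ratio, per the file headers, and the authors' p-value and adjusted p-value are given for all 3 comparisons. The Aspc1 tables are signed as control over siRNA, found from their correlation with the FPKM changes across genes (r = -0.677 and -0.748), and the Panc1 table as siRNA over control (r = 0.739). The deposited tables were used only to set their calls beside those made here.

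No read counts per library were used here, so the test planned for FPKM was used and not the one planned for counts. Values were put on the log2(FPKM + 1) scale, and genes with a mean of at least 0.5 FPKM over the libraries of a line were tested. Genes whose status was not OK in some library were left out (137 in Aspc1 and 125 in Panc1), which left 13066 and 13314 genes. The 45 repeated gene names were kept as separate entries. Starts in the files count from 0 and were changed to count from 1.

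Each line was fitted with limma 3.58.1 in R 4.3.3, with a trend of the spread on the level, and its 3 groups shared one estimate of the spread (residual degrees of freedom 3 in Aspc1 and 6 in Panc1, prior degrees of freedom 3.42 and 3.1). The comparisons were the mean of both siRNAs against control, each siRNA against control, and siRNA2 against siRNA1. P values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The overlap between the lines was tested with a two-sided Fisher's exact test per pair of directions. Controls of the lines were compared in a fit of their own.

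Of 40 gene lists (32 of biology, 8 of other cell types and RNA quality), the 35 with at least 5 genes tested in a line were tested with camera in limma at a preset correlation of 0.01. The test was repeated with a correlation estimated from the residuals of each list. With that estimate 0 of the 11 lists called over both siRNAs in Aspc1 held, and 3 of 12 in Panc1 (DNA replication, mitosis and DNA repair). In Aspc1, with 3 residual degrees of freedom, the repeated test passed no list in any comparison. Between the controls of the lines it did not pass the mucin list either (mean log2 difference -3.81, adjusted p = 0.517). A list that failed it is therefore not shown to be unchanged. Mean ± SD is over the libraries of a group. The design, the lists and the rule for named genes were set before the data were examined.

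Genes are named by a rule. It takes the target first, then the 10 largest rises and 10 largest falls over both siRNAs among called genes at 2 FPKM or more in the control or in both siRNA groups, with every siRNA library on the same side of every control library. It takes 5 each way for a single siRNA, for siRNA2 against siRNA1 and for the controls of the lines, up to 4 members of each called list and 3 neighbours of each target. FAM83H-AS1, FAM83H, LINC00673, LINC00511, SOX9, PTPN11, MYC, CDKN1A and MKI67 are among those always included. LINC00511 is not analysed here, and some genes that the rule takes are not reported here. Genes without a symbol, mitochondrial genes, small RNA genes and some sex-linked genes were left out, and of the genes the rule takes only part are described.

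The number of reads per library is not given in the sources used here. The deposited FPKM interval narrows with the number of fragments, so genes at 1 fragment could be found, and comparing their values between libraries gave each library's relative depth. The authors' mean normalised counts sum to 22.92 M (mega) in the Aspc1 tables and 21.98 M in the Panc1 table. Between 12167 and 12345 genes per library were at 1 FPKM or more.

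The fits were tested on simulated data in which 200 genes were changed. Over both siRNAs in Aspc1 (13066 genes), 46%, 90%, 100% and 100% of genes changed by a log2 of 0.25, 0.5, 1 and 2 were found, with 11 false calls. In Panc1 (13314 genes) the shares were 46%, 86%, 96% and 98%, with 9 false calls. A list shifted by a log2 of 0.2 was called in 8 of 8 simulations, and 1 of 280 unshifted lists was called. Values were drawn from a normal distribution with the spreads that the fits had estimated, and both siRNA groups were changed alike. These simulations therefore meet the assumptions of the fits and cannot give the rate of false calls in the real libraries. They also drew genes independently, so they do not test the list calls where genes of a list move together. In the real Panc1 libraries, the other splits of the closing section gave a median of 7 called lists. For the values that shared controls give with no effect, all libraries of a line, controls included, were simulated without change 20 times. Both siRNA groups were set against the same simulated controls. The real control libraries were not held fixed, so an offset of theirs is not in these simulations. For cholesterol synthesis genes over the 4 siRNAs this was done 1000 times with genes drawn independently.

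For the closing section, 3' UTRs of at least 50 bases were taken from GENCODE v44 lifted to GRCh37 for 86.4% of the genes tested in Aspc1 and 86.6% in Panc1. The heptamer (7 bases) most over-represented among genes that fell with an siRNA was found on odd-numbered chromosomes. It was then tested on even-numbered chromosomes and X with a pooled odds ratio over 10 bins of UTR length. This search was tested on simulated data, where the planted heptamer was found in 4 of 4 runs when common (in at least 5% of UTRs) and in 3 of 4 when rarer.

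Alternatives were a pseudocount of 0.1, no filter on level, a minimum mean FPKM of 1, median-of-ratios and quantile scaling, a robust fit, the replicate number as a block, a fit of only the groups compared, a minimum log2 change of 1, and leaving out each library in turn. Chosen after seeing the data were Panc1 replicates 1 and 2 alone and replicate 3 as a batch term. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 and the R package data.table (version 1.17.8) were also used.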

Results

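RNA sequencing was carried out on 15 libraries from a pair of human pancreatic cancer cell lines, 48 h after transfection with small interfering RNAs (siRNAs) against a long noncoding RNA or with a control siRNA. Aspc1 is an adenocarcinoma line first grown from ascites, and Panc1 is a line from a ductal carcinoma of the pancreas. In Aspc1 the target was FAM83H-AS1, with 2 libraries each for control, siRNA1 and siRNA2. In Panc1 the target was LINC00673, with 3 libraries each for control, siRNA1 and siRNA2. The question was which transcripts change when the level of each noncoding RNA is lowered, and the use of separate siRNAs against each target allows changes seen with both to be set apart from changes seen with 1 of them. The baseline of each line is its control siRNA, so an effect of that siRNA would be seen with both and cannot be told apart.

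Expression was given as FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 25593 gene entries per library, between 17177 and 18158 of them above 0. The depth of each library, relative to Aspc1 control replicate 1, was 1 and 1.005 in the Aspc1 controls, 0.985 and 1.22 with FAM83H-AS1 siRNA1, and 1.09 and 1.23 with siRNA2. In Panc1 it was 1.08, 0.968 and 0.973 in the controls, 1.196, 1.095 and 0.786 with LINC00673 siRNA1, and 1.11, 1.05 and 0.919 with siRNA2. Replicate libraries of a group correlated with r between 0.994 and 0.997 across genes on the log2 scale, and no pair held identical values. Log2 changes below are on the log2(FPKM + 1) scale, which understates the change of genes at low level, and adjusted p values are from limma. The labels do not say whether replicates were separate cultures, so the p values measure the spread between these samples, which may be technical.

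FAM83H-AS1 (LOC100128338 in the files, chromosome 8, 144816310 to 144828507 in hg19) was at 2.11 and 2.01 FPKM in the Aspc1 control libraries, at 0.750 and 0.926 with siRNA1, and at 0.693 and 0.788 with siRNA2. The group means were 2.06 ± 0.0697 in the control, 0.838 ± 0.124 with siRNA1 and 0.740 ± 0.0674 with siRNA2 (mean ± SD, n = 2 each), leaving 40.6% and 35.9% of the control level. The log2 change over both siRNAs was -0.78 with standard error 0.0775 (adjusted p = 0.00262), and -1.29 with a pseudocount of 0.1. FAM83H, the protein-coding neighbour (chromosome 8, 144806103 to 144815914), was at 43.9 ± 1.93 FPKM in the control, 45.2 ± 1.97 with siRNA1 and 49.3 ± 1.18 with siRNA2, and did not pass the test over both siRNAs (adjusted p = 0.141). With siRNA2 its log2 change was 0.17 (adjusted p = 0.0494), and this call ended without control replicate 1 or 2 (adjusted p = 0.0606 and 0.203), without siRNA2 replicate 1 or 2 (adjusted p = 0.147 and 0.217) and with no filter on level (adjusted p = 0.0935). The 2 genes do not overlap in the files' coordinates. Whether the counting used strand is not given in the sources used here, so reads from transcripts that run past these ends cannot be told apart.

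**Figure D1:**
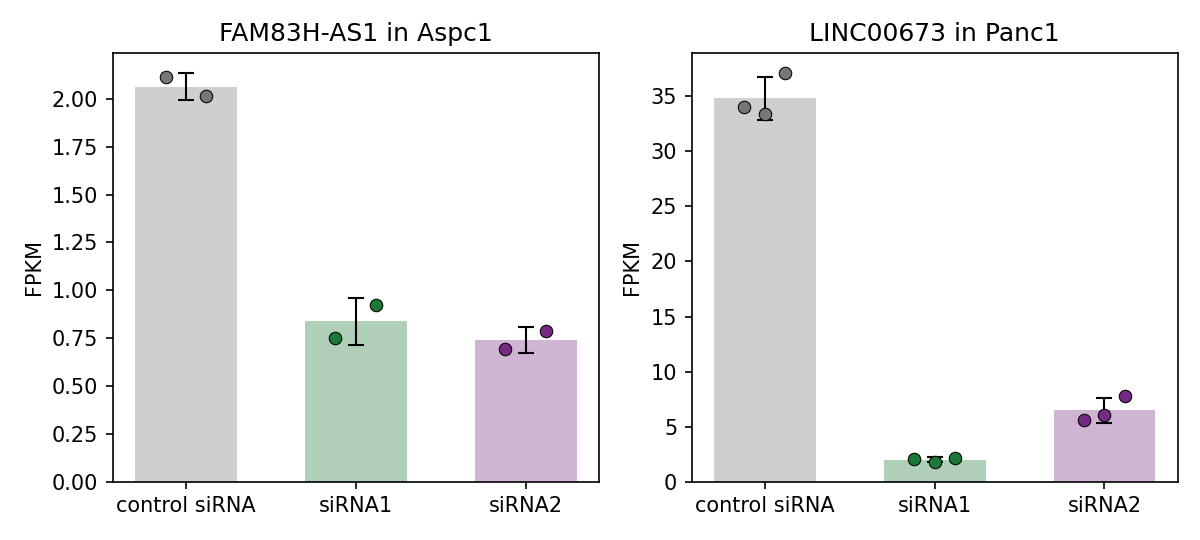
FPKM of FAM83H-AS1 in the 6 Aspc1 libraries and of LINC00673 in the 9 Panc1 libraries, by group. Bars are means, error bars SD and points single libraries, and every siRNA library lies below every control library of its line.

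With both FAM83H-AS1 siRNAs, KRT16 (chromosome 17, 39766030 to 39769079), a keratin of stressed and proliferating epithelium, rose from 5.01 ± 0.185 FPKM in the control to 14.3 ± 0.670 with siRNA1 and 11.8 ± 0.586 with siRNA2 (mean ± SD, n = 2 per group here and below), a log2 change of 1.22 with standard error 0.0516 (adjusted p = 0.000325). IGFBP1 (chromosome 7, 45927959 to 45933267), a secreted binding protein of insulin-like growth factors, fell from 101 ± 0.414 to 53.1 ± 3.29 and 46.5 ± 3.71 FPKM (log2 change -1.01 with standard error 0.0552, adjusted p = 0.000666). ERRFI1, a feedback inhibitor of the EGF receptor, fell from 92.3 ± 1.73 to 49.8 ± 1.36 and 49.3 ± 1.09 FPKM (log2 change -0.88 with standard error 0.0321, adjusted p = 0.000214). Genes of cholesterol synthesis rose as a group and ERK pathway output genes fell as a group, over both siRNAs and with each. The group calls were made with a preset correlation between genes and none of them held with an estimated correlation. That second test passed no list in any Aspc1 comparison, so it cannot tell these lists apart.

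Among the other large rises, PAK6, a p21-activated kinase, went from 2.19 ± 0.331 to 7.49 ± 0.144 FPKM with siRNA1 and 4.31 ± 0.148 with siRNA2. The carnosine synthase gene CARNS1 rose from 19.6 ± 0.601 to 40.5 ± 5.21 and 34.1 ± 1.84 FPKM. CCND3, which encodes the G1 cyclin D3, rose from 9.70 ± 0.0863 to 19.5 ± 0.690 and 17.1 ± 0.0222. NR0B2, the nuclear receptor SHP that represses bile acid synthesis, rose from 10.2 ± 0.808 to 15.5 ± 0.819 and 24.6 ± 0.579 FPKM. PEG10, a retrotransposon-derived imprinted gene, rose from 17.1 ± 1.36 to 23.1 ± 0.759 and 41.1 ± 1.08. APLP1, TMEM151A and MFAP2 had log2 changes of 0.84, 0.84 and 0.83 (adjusted p = 0.000591, 0.000245 and 0.00220). LOC100131774 had a log2 change of 0.997 (adjusted p = 0.0278). It overlaps CTGF on chromosome 6 (132266630 to 132269801, against 132269316 to 132272518), so the reads of the overlap cannot be assigned to either gene without strand. The authors' deposited tables list it at a mean of 0 with no fold change for both siRNAs. Its call ended without control replicate 1, control replicate 2 or siRNA2 replicate 1 (adjusted p = 0.0770, 0.156 and 0.0893), with no filter on level (adjusted p = 0.0922) and with the robust fit (adjusted p = 0.0990).

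Among the other large falls, G0S2, an inhibitor of the lipase ATGL, went from 12.6 ± 0.507 to 6.61 ± 0.945 FPKM with siRNA1 and 5.35 ± 0.497 with siRNA2 (log2 change -0.98, adjusted p = 0.00181). S100P, a calcium-binding protein often high in pancreatic cancer, fell from 39.4 ± 2.90 to 21.3 ± 3.003 and 20.04 ± 2.09 FPKM. TRIB3, a pseudokinase induced by ATF4, fell from 106 ± 1.09 to 80.4 ± 2.96 and 49.1 ± 3.30. The log2 changes of S100P and TRIB3 were -0.90 and -0.74 (adjusted p = 0.00307 and 0.000814). C11orf86, NUPR1 and NDRG1 had log2 changes of -0.83, -0.95 and -0.75 (adjusted p = 0.00998, 0.0124 and 0.0386). LOC100652757 had the largest fall in size, -2.27 (adjusted p = 0.0322), or -3.99 with a pseudocount of 0.1, but its siRNA1 mean was 5.34 ± 5.67 FPKM, so the siRNA1 libraries differed widely. It overlaps TXNIP in the files' coordinates, and the authors' deposited tables list it at a mean of 0 with no fold change for both siRNAs. Of the genes fixed by name, PTPN11 had a log2 change of -0.18 (adjusted p = 0.00941). Without control replicate 1 the calls of C11orf86, NDRG1, LOC100652757 and PTPN11 ended (adjusted p from 0.0504 to 0.188), and without control replicate 2 those of NUPR1, NDRG1, LOC100652757 and PTPN11 (0.0691 to 0.144). Without siRNA2 replicate 1 those of C11orf86, NUPR1, NDRG1, LOC100652757 and PTPN11 ended (0.0529 to 0.128), and without siRNA2 replicate 2 those of NDRG1 and LOC100652757 (0.0663 and 0.0859). With no filter on level the calls of NUPR1, NDRG1 and LOC100652757 ended (adjusted p = 0.0535, 0.116 and 0.103), and with the robust fit those of NDRG1 and LOC100652757 (adjusted p = 0.167 and 0.154). SOX9, MYC, CDKN1A and MKI67 did not pass (adjusted p = 0.0643, 0.415, 0.0570 and 0.702), nor did LINC00673 (adjusted p = 0.971), which was at 5.92 ± 0.236 FPKM in the Aspc1 control and differed between the siRNAs (log2 difference 0.23, adjusted p = 0.0351). That call ended without any 1 of the 6 libraries (adjusted p from 0.0521 to 0.175) and with no filter on level (adjusted p = 0.0747). SOX9 passed without siRNA1 replicate 1 (adjusted p = 0.0214), with quantile scaling (adjusted p = 0.0421) and with the robust fit (adjusted p = 0.0419), and CDKN1A without siRNA1 replicate 2 (adjusted p = 0.0472).

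Of the 24 cholesterol synthesis and SREBP2 target genes tested in Aspc1, 15 rose and 1 fell over all genes (19 and 1 adjusted over the list alone), with a mean log2 change of 0.22 (adjusted p = 2.51e-08, and adjusted p = 0.439 with an estimated correlation). SQLE, the squalene epoxidase, rose from 37.8 ± 1.56 to 51.6 ± 2.64 and 55.8 ± 1.26 FPKM, and MSMO1 from 50.9 ± 2.03 to 61.3 ± 0.635 and 86.4 ± 5.18. Of 13 fatty acid synthesis genes 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 8.41e-05, adjusted p = 0.477 with an estimated correlation). The desaturase gene SCD rose from 619 ± 17.7 to 715 ± 18.1 and 774 ± 4.71 FPKM. Of 11 WNT targets 4 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 0.00413, adjusted p = 0.477 with an estimated correlation), among them the stem cell marker LGR5, from 11.6 ± 0.967 to 18.9 ± 0.486 and 20.01 ± 0.00396 FPKM, and CD44. Of 12 heat shock genes 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.000290, adjusted p = 0.473 with an estimated correlation), among them HSP90AA1, from 297 ± 7.61 to 341 ± 3.52 and 344 ± 2.42 FPKM. Of 27 lysosome and autophagy genes 12 rose and 5 fell (14 and 5 adjusted over the list alone, adjusted p = 0.0142, adjusted p = 0.473 with an estimated correlation), and the cathepsin gene CTSD had a log2 change of 0.38. Of 23 TGF-beta targets 8 rose and 1 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0353, adjusted p = 0.477 with an estimated correlation). The TGF-beta call ended without control replicate 1, control replicate 2 or siRNA1 replicate 2 (adjusted p = 0.115, 0.0624 and 0.0568). Taken singly, siRNA1 did not call the WNT and heat shock lists (adjusted p = 0.102 each), and siRNA2 did not call the TGF-beta and lysosome lists (adjusted p = 0.462 and 0.0524). The lysosome list passed with siRNA2 with no filter on level and without control replicate 1 (adjusted p = 0.0363 and 0.0343). ID2, a repressor of basic helix-loop-helix factors, rose from 3.91 ± 0.176 to 6.12 ± 0.0422 and 7.05 ± 0.0751 FPKM.

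Of 36 interferon-stimulated genes tested in Aspc1, 2 rose and 14 fell (2 and 16 adjusted over the list alone), with a mean log2 change of -0.15 (adjusted p = 0.000124, adjusted p = 0.439 with an estimated correlation). With siRNA1 3 rose and 3 fell (3 and 4 adjusted over the list alone, mean log2 change -0.01, adjusted p = 0.582), and with siRNA2 2 rose and 19 fell (2 and 20 adjusted over the list alone, mean log2 change -0.29, adjusted p = 5.58e-07, adjusted p = 0.267 with an estimated correlation). OAS3, a sensor of double-stranded RNA, fell from 15.7 ± 0.0675 to 12.4 ± 0.0403 and 9.90 ± 0.656 FPKM. OASL, of the same family, was at 58.9 ± 2.17 in the control, 59.4 ± 2.52 with siRNA1 and 32.2 ± 0.727 with siRNA2. Of 26 ERK pathway output and immediate early genes 2 rose and 13 fell (2 and 15 adjusted over the list alone, mean log2 change -0.15, adjusted p = 0.000124, adjusted p = 0.477 with an estimated correlation). AREG, a ligand of the EGF receptor, fell from 65.6 ± 2.87 to 38.6 ± 2.95 and 46.6 ± 0.395 FPKM. Its level is uncertain, since the near-identical AREGB was at 63.7 ± 2.63 in the control and the authors' deposited tables list AREG at a mean of 24.0 normalised counts with no adjusted p. The immediate early gene EGR1 fell from 21.5 ± 0.135 to 15.8 ± 1.199 and 14.2 ± 0.356 FPKM. Of 24 unfolded protein response and ATF4 target genes 6 rose and 12 fell (7 and 14 adjusted over the list alone, mean log2 change -0.17, adjusted p = 0.0144, adjusted p = 0.477 with an estimated correlation). ASNS, the asparagine synthetase, fell from 708 ± 32.1 to 592 ± 3.21 and 454 ± 16.1 FPKM, and SESN2 from 25.1 ± 0.215 to 19.6 ± 0.764 and 15.7 ± 0.348. PDIA4, of the same list, rose by a log2 change of 0.60 (adjusted p = 0.000388), so the list did not move as a whole. Of 32 hypoxia and glycolysis genes 0 rose and 5 fell (1 and 11 adjusted over the list alone, mean log2 change -0.13, adjusted p = 0.0184, adjusted p = 0.674 with an estimated correlation), among them PDK1, from 16.6 ± 0.269 to 13.4 ± 1.33 and 11.8 ± 0.579 FPKM. The hypoxia call ended without control replicate 1 (mean log2 change -0.06, adjusted p = 0.692) or siRNA1 replicate 2 (adjusted p = 0.0977). The PDK1 call ended without control replicate 1, control replicate 2 or siRNA2 replicate 1 (adjusted p = 0.0722, 0.0642 and 0.0553). Of 50 cytosolic ribosomal protein genes 0 rose and 10 fell (0 and 11 adjusted over the list alone, mean log2 change -0.06, adjusted p = 7.99e-05, adjusted p = 0.439 with an estimated correlation), among them RPL3, from 749 ± 27.3 to 630 ± 0.748 and 616 ± 12.6 FPKM.

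**Figure D2:**
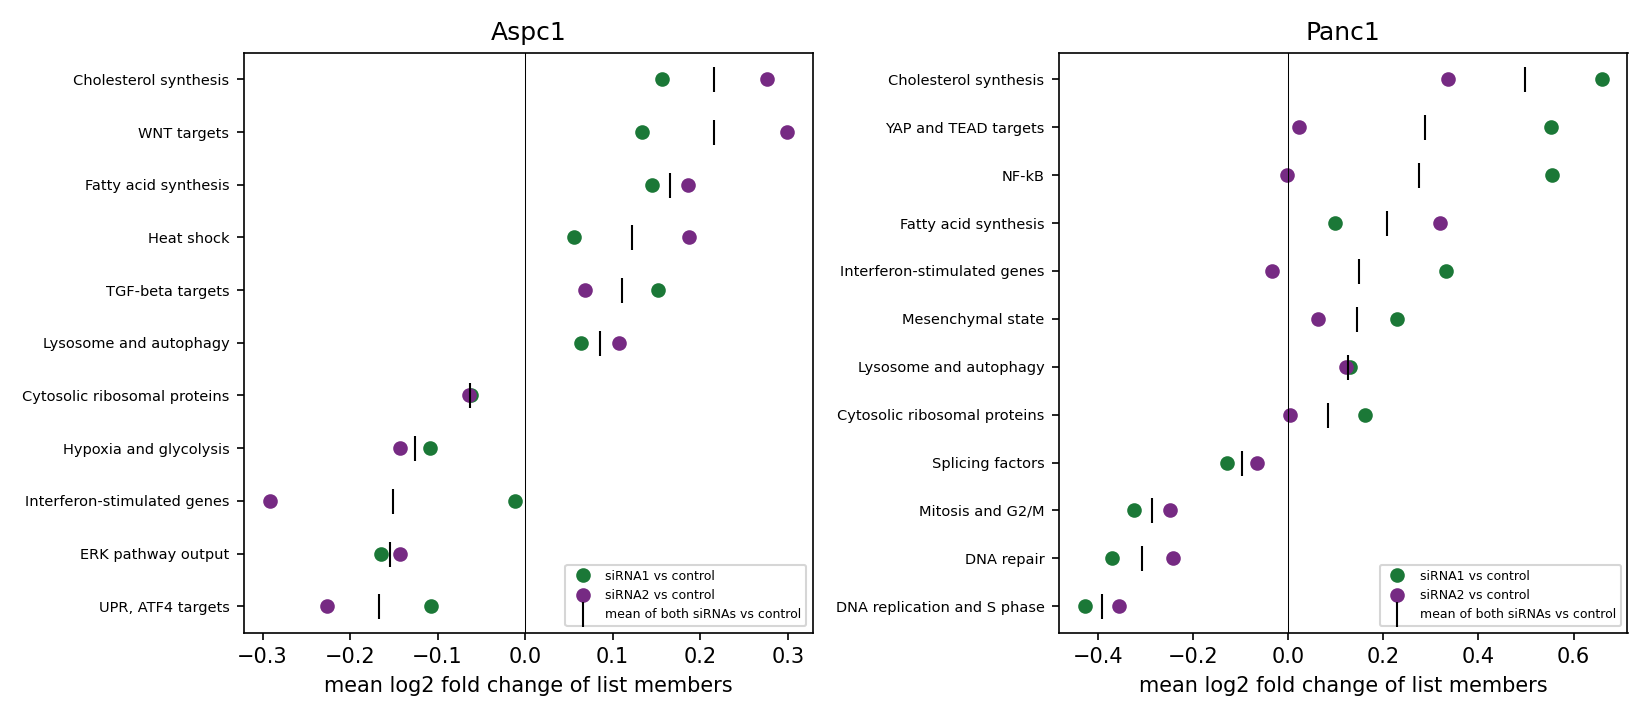
Mean log2 change on the log2(FPKM + 1) scale of the gene lists called over both siRNAs in Aspc1 (11 lists) and Panc1 (12 lists). Dots are siRNA1 and siRNA2 against control and bars their mean. In Aspc1 the means run from cholesterol synthesis at 0.22 to the mixed list of unfolded protein response and ATF4 target genes at -0.17. In Panc1 they run from cholesterol synthesis at 0.50 to DNA replication at -0.39.

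The 8q24.3 neighbours of FAM83H-AS1 were not called as a group in Aspc1 (mean log2 change 0.03 over 19 genes, adjusted p = 0.654). The 3 with the smallest p were TOP1MT (log2 change -0.14, adjusted p = 0.0293), RHPN1 (0.26, adjusted p = 0.0489) and NRBP2 (0.22, adjusted p = 0.0719). Without control replicates 1 and 2 and siRNA2 replicates 1 and 2 the adjusted p of TOP1MT was 0.137, 0.116, 0.0822 and 0.0997, and that of RHPN1 0.101, 0.240, 0.138 and 0.122. The RHPN1 call also ended without siRNA1 replicate 2 (adjusted p = 0.0761), with no filter on level (adjusted p = 0.115) and with quantile scaling (adjusted p = 0.0509). NRBP2 passed without siRNA1 replicate 1 or 2 (adjusted p = 0.0107 and 0.0330) and with the robust fit (adjusted p = 0.0477). Islet genes, several of which the Aspc1 libraries hold at levels that vary between replicates, were not called as a list (mean log2 change 0.38 over 6 genes, adjusted p = 0.288), but were without siRNA2 replicate 2 (adjusted p = 0.00590). Insulin (INS) was at 8.65 and 21.7 FPKM in the control libraries, 11.6 and 16.4 with siRNA1, and 59.7 and 14.1 with siRNA2.

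Over all 13066 genes tested in Aspc1, 2224 passed over both FAM83H-AS1 siRNAs, 1160 higher and 1064 lower, of which 9 reached a log2 change of at least 1 in size. In a fit of the 6 libraries that pools both siRNAs as a single group, so that differences between the siRNAs count as spread, 114 genes passed. The count over both siRNAs dropped to 811 without control replicate 1, 744 without control replicate 2, 811 without siRNA2 replicate 1 and 1124 without siRNA2 replicate 2.

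With FAM83H-AS1 siRNA1 alone, 1357 genes passed, 743 higher and 614 lower. The largest rises and falls included REG4, a secreted lectin of the gut epithelium, from 2.72 ± 0.132 to 6.93 ± 0.806 FPKM (log2 change 1.09, adjusted p = 0.00259), and CCL20, a chemokine, from 7.92 ± 0.124 to 3.12 ± 0.0357 (log2 change -1.11, adjusted p = 0.00366). OSTM1 fell from 12.5 ± 0.351 to 5.94 ± 0.351 FPKM (log2 change -0.97, adjusted p = 0.00135) and was at 12.2 ± 0.479 with siRNA2. With siRNA2 alone 3249 genes passed, 1665 higher and 1584 lower. AGR2, an endoplasmic reticulum protein needed for mucin secretion, rose from 86.6 ± 2.94 to 187 ± 11.4 FPKM (log2 change 1.10, adjusted p = 0.000181). MOB2, a partner of NDR kinases, fell from 14.03 ± 0.260 to 4.31 ± 0.461 FPKM (log2 change -1.50, adjusted p = 0.000181), and BCL7B from 57.8 ± 0.136 to 25.3 ± 0.937 (log2 change -1.16, adjusted p = 6.88e-05). The siRNA1 count was between 384 and 636 without any single library, with 384 and 454 without control replicates 1 and 2, 636 and 600 without siRNA1 replicates 1 and 2, and 500 and 630 without siRNA2 replicates 1 and 2. The siRNA2 count was 1939 and 1703 without control replicates 1 and 2, and 947 and 1460 without siRNA2 replicates 1 and 2.

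The FAM83H-AS1 siRNAs also differed from each other. Between them 3109 of the 13066 genes passed, 1542 higher and 1567 lower with siRNA2. LUM, which encodes the matrix proteoglycan lumican, was at 129 ± 5.19 FPKM with siRNA1 and 309 ± 14.1 with siRNA2, against 145 ± 0.274 in the control (log2 difference 1.25, adjusted p = 7.17e-05). F11R, the junctional adhesion molecule JAM-A, was at 67.8 ± 2.03 with siRNA1 and 25.5 ± 1.30 with siRNA2, against 55.9 ± 0.228 in the control (log2 difference -1.38, adjusted p = 7.17e-05). Of 36 nuclear-encoded oxidative phosphorylation genes 0 were higher and 19 lower with siRNA2 than with siRNA1 (0 and 21 adjusted over the list alone, mean log2 difference -0.16, adjusted p = 3.86e-08, adjusted p = 0.134 with an estimated correlation). Of the interferon-stimulated genes 1 was higher and 14 were lower with siRNA2 (1 and 23 adjusted over the list alone, mean log2 difference -0.28, adjusted p = 5.80e-07, adjusted p = 0.134 with an estimated correlation). Without siRNA2 replicate 1 the count of genes that differ was 779, without siRNA2 replicate 2 it was 1173, and without siRNA1 replicate 1 it was 1873.

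Both FAM83H-AS1 siRNAs called 650 genes in the same direction, 380 higher and 270 lower, and 104 in opposite directions. Independent lists of these sizes would share 94.7 higher and 74.4 lower genes, with 168.3 in opposite directions. Simulated unchanged groups set against shared simulated controls had at most 1 gene in common in 20 simulations. That number is held near 0 because unchanged groups yield few calls. Over all genes tested, 63.8% had the same sign with both siRNAs, against 66.8% in the simulated groups. Across genes the log2 changes of the siRNAs correlated with r = 0.368, against 0.531 for the simulated unchanged groups. Their covariance was 0.0244 against 0.0126 simulated, a difference of 0.0118. Genes are not independent replicates, and the 2 control libraries were not split between the siRNAs, so part of the excess may come from the shared controls. The shared count was 204 and 219 without control replicates 1 and 2, 356 and 329 without siRNA1 replicates 1 and 2, and 165 and 238 without siRNA2 replicates 1 and 2. In the authors' deposited tables, 1309 genes had an adjusted p under the same threshold for siRNA1 and 2721 for siRNA2. Of these, 1056 and 2450 also passed here, and 1056 and 2450 had the same direction once the tables' sign, control over siRNA, was turned.

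**Figure D3:**
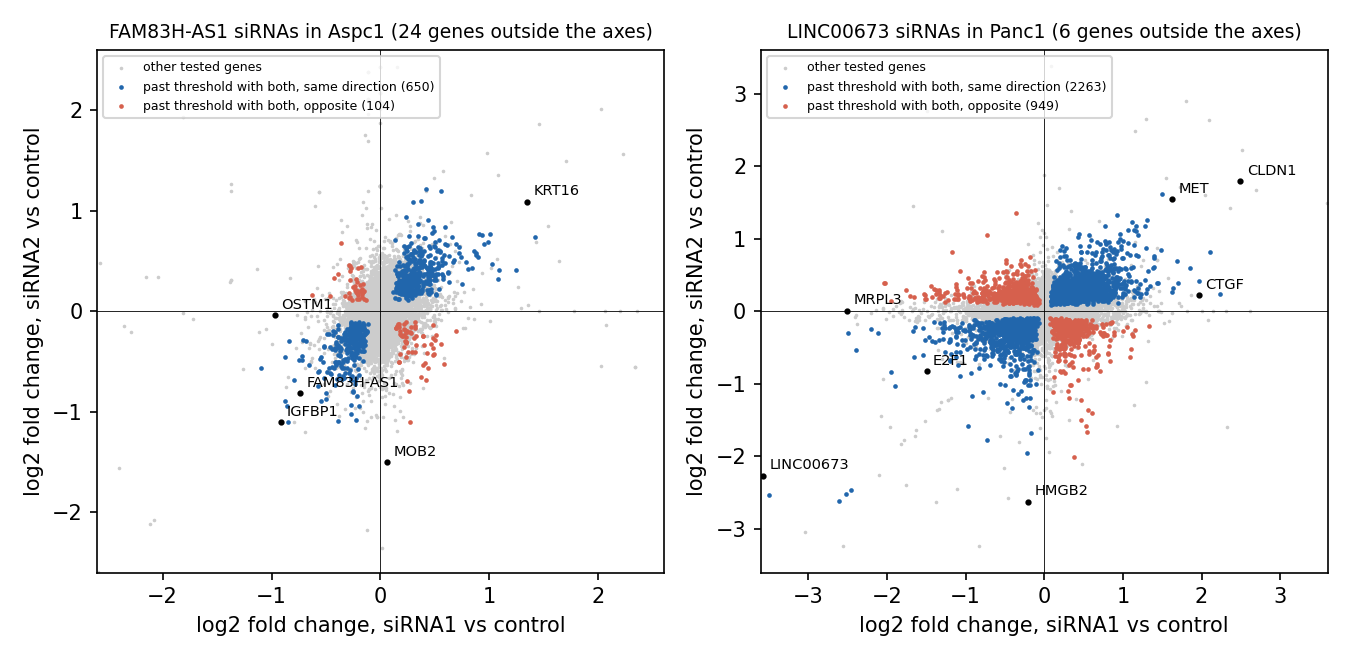
Log2 change with siRNA1 (horizontal) and siRNA2 (vertical) against control, on the log2(FPKM + 1) scale, for 13066 genes in Aspc1 and 13314 in Panc1, with genes called with each siRNA coloured by whether the directions are the same. Both siRNAs called 650 genes in the same and 104 in opposite directions in Aspc1, and 2263 and 949 in Panc1, and 24 and 6 genes lie outside the axes.

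LINC00673 (LOC100499467 in the files, chromosome 17, 70399463 to 70588943 in hg19) was at 34.0, 33.4 and 37.04 FPKM in the Panc1 control libraries, at 2.09, 1.77 and 2.19 with siRNA1, and at 5.64, 6.08 and 7.77 with siRNA2. The group means were 34.8 ± 1.96, 2.01 ± 0.219 and 6.50 ± 1.12 (mean ± SD, n = 3 each), leaving 5.79% of the control level with siRNA1 and 18.7% with siRNA2. The log2 change over both siRNAs was -2.92 with standard error 0.0872 (adjusted p = 5.44e-08), and the level with siRNA2 was above that with siRNA1 by a log2 difference of 1.31 (adjusted p = 4.71e-06). The next genes on either side are SOX9 (70117161 to 70122561) and FLJ26484 (70594180 to 70636611), neither of which overlaps it. FAM83H-AS1 was at 0.680 ± 0.0591 FPKM in the Panc1 control and did not pass over both siRNAs (adjusted p = 0.204). It was at 1.08 ± 0.0923 with siRNA1 (log2 change 0.31, adjusted p = 0.0120) and 0.615 ± 0.163 with siRNA2 (adjusted p = 0.624), and the siRNAs differed (log2 difference -0.37, adjusted p = 0.00467). The siRNA1 call ended with replicates 1 and 2 alone (adjusted p = 0.102), and with a pseudocount of 0.1 the log2 values were 0.60 and -0.74.

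With both LINC00673 siRNAs, CLDN1 (chromosome 3, 190023490 to 190040235), a tight junction claudin, rose from 15.2 ± 0.702 FPKM in the control to 90.7 ± 7.50 with siRNA1 and 55.4 ± 0.788 with siRNA2 (mean ± SD, n = 3 per group here and below), a log2 change of 2.15 with standard error 0.05002 (adjusted p = 1.58e-08). MET (chromosome 7, 116312459 to 116438440), the receptor of hepatocyte growth factor, rose from 20.2 ± 0.716 to 64.5 ± 1.46 and 60.8 ± 1.49 FPKM (log2 change 1.59 with standard error 0.0312, adjusted p = 1.18e-08). DNA replication, mitosis and DNA repair genes fell as groups. Cholesterol synthesis genes rose as a group (adjusted p = 9.17e-11, adjusted p = 0.0721 with an estimated correlation). E2F1, a transcription factor of S phase entry, fell from 42.0 ± 0.897 to 14.3 ± 0.789 and 23.4 ± 0.809 FPKM (log2 change -1.16 with standard error 0.0390, adjusted p = 1.02e-07).

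**Figure D4:**
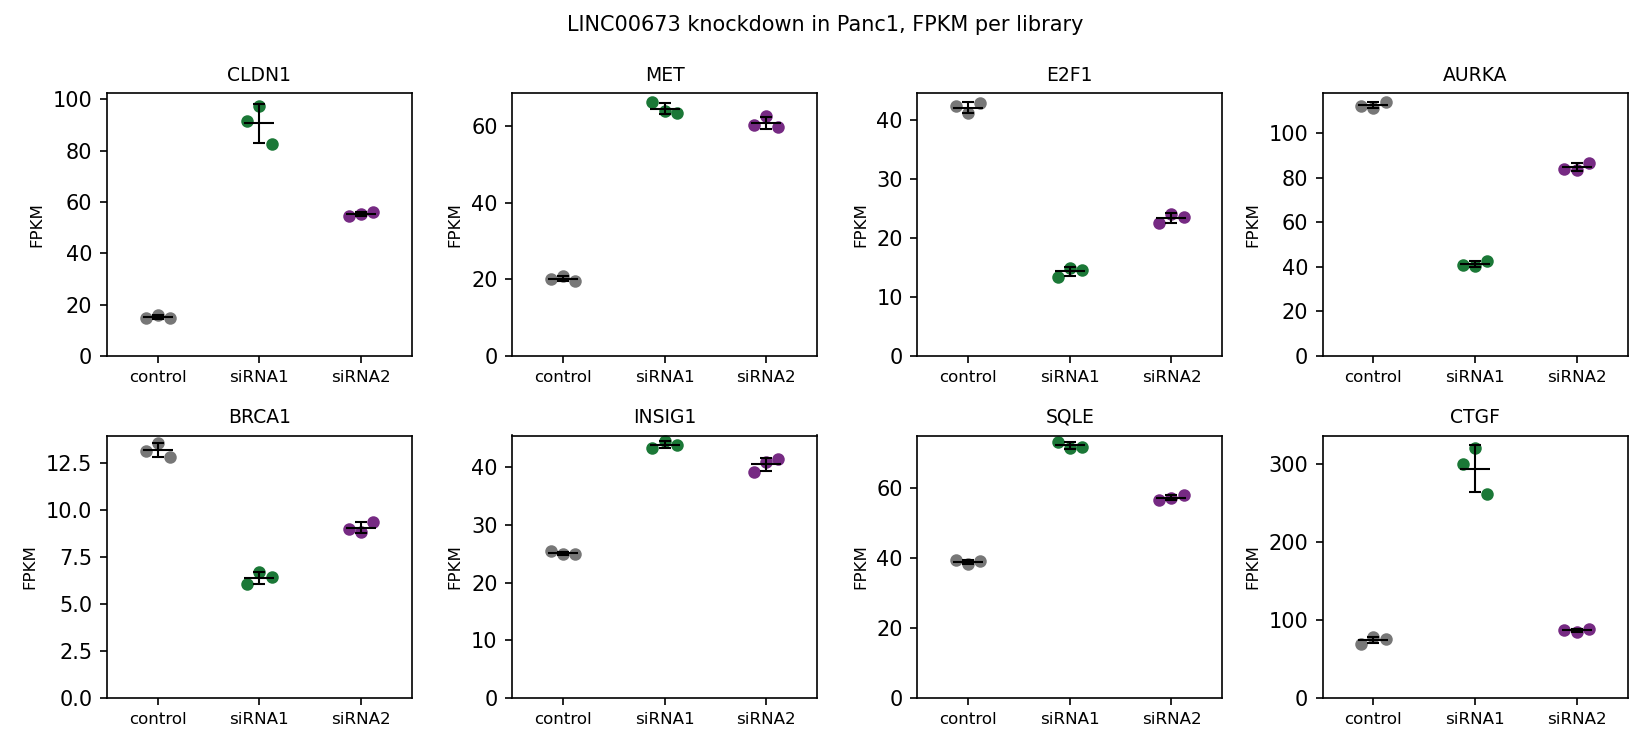
FPKM of CLDN1, MET, E2F1, AURKA, BRCA1, INSIG1, SQLE and CTGF in the 9 Panc1 libraries, by group. Bars are means, error bars SD and points single libraries, and of these genes CTGF has the largest difference between the siRNAs, at 294 ± 29.7 with siRNA1 and 86.7 ± 2.15 with siRNA2.

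Of 44 DNA replication and S phase genes tested in Panc1, 0 rose and 41 fell (0 and 42 adjusted over the list alone), with a mean log2 change of -0.39 (adjusted p = 6.21e-17, and adjusted p = 0.00470 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 294 ± 0.283 to 187 ± 1.57 with siRNA1 and 237 ± 2.45 with siRNA2. GINS1, of the replicative helicase, fell from 28.6 ± 0.362 to 10.8 ± 0.433 and 21.7 ± 1.25, and MCM10 from 13.0 ± 0.101 to 8.36 ± 0.0786 and 7.88 ± 0.303 FPKM. Of 38 mitosis and G2/M genes 1 rose and 34 fell (1 and 36 adjusted over the list alone, mean log2 change -0.29, adjusted p = 1.04e-12, adjusted p = 0.0131 with an estimated correlation). AURKA, a mitotic kinase, fell from 113 ± 1.43 to 41.4 ± 1.21 and 84.8 ± 1.85 FPKM. TOP2A fell from 155 ± 4.95 to 96.4 ± 3.05 and 124 ± 2.57, and FOXM1 from 48.6 ± 2.14 to 29.3 ± 0.563 and 38.9 ± 0.851. Of 25 DNA repair genes 0 rose and 19 fell (1 and 20 adjusted over the list alone, mean log2 change -0.31, adjusted p = 3.45e-08, adjusted p = 0.0330 with an estimated correlation). BRCA1 fell from 13.2 ± 0.377 to 6.39 ± 0.332 and 9.07 ± 0.271 FPKM, and FANCI, of the Fanconi anaemia pathway, from 59.6 ± 0.659 to 36.8 ± 0.406 and 42.3 ± 0.644. Between the siRNAs none of these 3 lists was called (adjusted p = 0.740 for replication, 0.229 for mitosis and 0.229 for repair). MKI67, the gene of the proliferation antigen Ki-67, had a log2 change of -0.55 (adjusted p = 0.000303). CDKN1A, which encodes the CDK inhibitor p21, had one of 0.35 (adjusted p = 0.000613), from 27.6 ± 2.43 in the control to 42.6 ± 0.951 with siRNA1 and 29.3 ± 1.59 with siRNA2. Of 27 splicing factor genes 3 rose and 14 fell (3 and 14 adjusted over the list alone, mean log2 change -0.10, adjusted p = 0.0290, adjusted p = 0.501 with an estimated correlation), among them SRSF4, from 38.5 ± 1.70 to 25.9 ± 0.0959 and 24.1 ± 1.44 FPKM. The splicing list was not called with siRNA1 or siRNA2 taken singly (adjusted p = 0.0557 and 0.123), but it was with siRNA1 with no filter on level, median-of-ratios scaling, quantile scaling, replicates 1 and 2 alone and without control replicate 3 (adjusted p = 0.0223, 0.0393, 0.0457, 0.0436 and 0.0434).

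Of 24 cholesterol synthesis and SREBP2 target genes tested in Panc1, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a mean log2 change of 0.50 (adjusted p = 9.17e-11, and adjusted p = 0.0721 with an estimated correlation). SQLE rose from 38.9 ± 0.541 to 72.2 ± 0.936 and 57.3 ± 0.744 FPKM, and INSIG1 from 25.1 ± 0.268 to 43.9 ± 0.606 and 40.5 ± 1.11. HMGCS1 was at 31.5 ± 0.691 in the control, 89.7 ± 0.190 with siRNA1 and 31.3 ± 1.35 with siRNA2. Of 12 fatty acid synthesis genes 8 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0428, adjusted p = 0.590 with an estimated correlation). FASN, the fatty acid synthase, rose from 59.2 ± 0.951 to 96.6 ± 5.91 and 74.7 ± 3.16 FPKM. Of 27 lysosome and autophagy genes 14 rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 0.0335, adjusted p = 0.501 with an estimated correlation). GABARAPL1, an autophagosome protein, rose from 21.7 ± 1.04 to 45.7 ± 1.94 and 28.2 ± 3.62 FPKM. Of 50 cytosolic ribosomal protein genes 17 rose and 1 fell (15 and 0 adjusted over the list alone, mean log2 change 0.08, adjusted p = 0.0357, adjusted p = 0.786 with an estimated correlation), and RPL15 had a log2 change of 0.27. The ribosomal call ended without control replicate 2, siRNA1 replicate 3 or siRNA2 replicate 3 (adjusted p = 0.349, 0.0664 and 0.0750), and its mean was 0.04 without control replicate 2 and 0.13 without control replicate 3. The lysosome call ended without control replicate 2 (adjusted p = 0.0505). The fatty acid call ended without control replicate 3 or siRNA2 replicate 3 (adjusted p = 0.0689 and 0.0509) and with replicates 1 and 2 alone (adjusted p = 0.0949) or replicate 3 as a batch term (adjusted p = 0.0538). Taken singly, siRNA1 did not call the fatty acid and lysosome lists (adjusted p = 0.308 and 0.234), and siRNA2 did not call the ribosomal list (adjusted p = 0.936).

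Of 18 YAP and TEAD target genes tested in Panc1, 13 rose and 1 fell (15 and 1 adjusted over the list alone), with a mean log2 change of 0.29 (adjusted p = 0.000447, adjusted p = 0.175 with an estimated correlation). CTGF was at 74.3 ± 4.41 FPKM in the control, 294 ± 29.7 with siRNA1 and 86.7 ± 2.15 with siRNA2, and CYR61 at 277 ± 10.3, 646 ± 36.7 and 273 ± 8.06. The list was lower with siRNA2 than with siRNA1 (mean log2 difference -0.53, adjusted p = 0.000511, adjusted p = 0.369 with an estimated correlation). Of 35 interferon-stimulated genes 20 rose and 2 fell (21 and 2 adjusted over the list alone, mean log2 change 0.15, adjusted p = 0.00713, adjusted p = 0.175 with an estimated correlation). DDX58, the RNA sensor RIG-I, was at 21.7 ± 0.899 in the control, 37.5 ± 0.601 with siRNA1 and 22.0 ± 0.965 with siRNA2, and 27 of the list's genes were lower and 2 higher with siRNA2 than with siRNA1 (27 and 2 adjusted over the list alone, adjusted p = 0.000124, adjusted p = 0.233 with an estimated correlation). Of 19 NF-kB and inflammatory cytokine genes 10 rose and 2 fell (10 and 2 adjusted over the list alone, mean log2 change 0.28, adjusted p = 0.0458, adjusted p = 0.590 with an estimated correlation), and the adhesion molecule gene ICAM1 was at 89.8 ± 3.85, 155 ± 5.16 and 102 ± 2.74 FPKM in the control, siRNA1 and siRNA2. Of 22 mesenchymal state genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, mean log2 change 0.15, adjusted p = 0.0335, adjusted p = 0.314 with an estimated correlation). SPARC, a matrix glycoprotein, was at 34.7 ± 2.12, 62.7 ± 3.13 and 39.2 ± 0.0446 FPKM. The NF-kB call ended without control replicate 1, siRNA1 replicate 2, siRNA2 replicate 1 or siRNA2 replicate 3 (adjusted p = 0.0636, 0.0621, 0.0501 and 0.0533), with a pseudocount of 0.1 (adjusted p = 0.0580), with replicate 3 as a batch term (adjusted p = 0.0574), and with a minimum mean FPKM of 1 (adjusted p = 0.0838). The mesenchymal call also ended with that minimum (adjusted p = 0.0608). With siRNA2 taken singly, the YAP, interferon, NF-kB and mesenchymal lists were not called (adjusted p = 0.602, 0.602, 0.627 and 0.461).

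Among the other large changes over both LINC00673 siRNAs, the mitochondrial phosphatase gene PTPMT1 rose from 10.2 ± 0.377 to 30.6 ± 1.09 and 33.4 ± 1.55 FPKM. SRPR, of the signal recognition particle receptor, rose from 54.6 ± 1.27 to 137 ± 1.42 and 132 ± 3.34, and TOMM20, a mitochondrial import receptor, from 39.2 ± 0.309 to 97.0 ± 2.61 and 90.1 ± 3.49. PRSS22, a serine protease, and LTB, the cytokine lymphotoxin beta, had log2 changes of 1.47 and 1.22 (adjusted p = 3.52e-07 and 3.25e-06). ELF4, an ETS factor, fell from 51.5 ± 0.369 to 13.1 ± 0.472 and 24.8 ± 1.08 FPKM. Several of the largest falls came mostly from a single siRNA. CDV3 went from 279 ± 11.03 to 52.5 ± 0.704 with siRNA1 and 192 ± 7.66 with siRNA2, and TTYH3 from 105 ± 1.06 to 17.8 ± 0.867 and 85.0 ± 2.33. HMGB2 went from 195 ± 5.12 to 169 ± 2.62 with siRNA1 and 30.9 ± 0.520 with siRNA2. Of the genes fixed by name, MYC had a log2 change of 0.38 (adjusted p = 7.33e-06) and SOX9 0.25 (adjusted p = 0.0122), while PTPN11 did not pass (adjusted p = 0.541).

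The 17q24.3 neighbours of LINC00673 were not called as a group in Panc1 (mean log2 change 0.05 over 8 genes, adjusted p = 0.492). COG1 and SSTR2 had log2 changes of 0.25 and -0.36 (adjusted p = 0.000716 and 0.00440). SOX9 was at 34.0 ± 1.81 FPKM in the control, 49.0 ± 2.77 with siRNA1 and 34.0 ± 3.72 with siRNA2 (log2 difference between the siRNAs -0.52, adjusted p = 0.000356), and its call over both siRNAs ended without control replicate 3 (adjusted p = 0.0517). The replicate 3 libraries, 1 in each Panc1 group, held 6 of the 9 islet genes (CHGA, GCG, INS, PPY, SST and TTR) at higher levels than the other 6 libraries, with INS at 4.52, 3.79 and 6.58 FPKM in control, siRNA1 and siRNA2 and listed at 0 in replicates 1 and 2. Of the same list, CHGB was at 1.97 FPKM in siRNA1 replicate 3 against 2.27 in siRNA2 replicate 1, and SCG2 at 0.484 in control replicate 3 against 0.699 in siRNA2 replicate 2.

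Over the 13314 genes tested in Panc1, 6401 passed over both LINC00673 siRNAs, 3364 higher and 3037 lower, of which 60 reached a log2 change of at least 1 in size. With replicates 1 and 2 alone the count was 5894, and replicate 3 has 1 library per group and so gives no value of its own. In a fit that pools both siRNAs as a single group, 1478 genes passed. With siRNA1 alone 7922 genes passed (4192 higher, 3730 lower), or 7530 with replicates 1 and 2 alone, and with siRNA2 alone 4452 passed (2410 higher, 2042 lower), or 3815 with replicates 1 and 2 alone.

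Single-siRNA changes in Panc1 included TNFRSF10D, a decoy receptor of TRAIL, which rose from 1.86 ± 0.175 to 12.4 ± 0.269 FPKM with siRNA1 (log2 change 2.23, adjusted p = 8.64e-09), and PTX3, a pentraxin of innate immunity, from 7.08 ± 0.517 to 33.3 ± 3.40 (log2 change 2.08, adjusted p = 5.76e-08). With siRNA1 MRPL3, a mitochondrial ribosomal protein gene, fell from 130 ± 1.60 to 22.1 ± 0.987 FPKM (log2 change -2.51, adjusted p = 8.97e-10), against 131 ± 1.63 with siRNA2. LASP1, an actin-binding protein, fell from 78.1 ± 3.98 to 13.96 ± 0.302 FPKM with siRNA1 (log2 change -2.40, adjusted p = 8.97e-10), against 73.9 ± 1.33 with siRNA2. With siRNA2 CALU, a calcium-binding protein of the secretory pathway, rose from 45.3 ± 0.341 to 117 ± 1.83 FPKM (log2 change 1.35, adjusted p = 2.45e-08). AK4, a mitochondrial adenylate kinase, fell from 8.22 ± 0.450 to 1.30 ± 0.0382 with siRNA2 (log2 change -2.00, adjusted p = 2.45e-08), and ERH from 166 ± 3.12 to 42.3 ± 1.79 (log2 change -1.95, adjusted p = 6.19e-09).

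Between the LINC00673 siRNAs 7829 of the 13314 genes passed, 3707 higher and 4122 lower with siRNA2, or 7379 with replicates 1 and 2 alone. Among the largest differences, AIDA was at 25.7 ± 0.501 FPKM in the control, 5.55 ± 0.634 with siRNA1 and 34.1 ± 1.07 with siRNA2, and BLCAP at 29.98 ± 1.53, 44.02 ± 1.97 and 8.78 ± 0.264. The sulfate transporter gene SLC26A2 was at 52.2 ± 2.97, 75.9 ± 1.65 and 16.7 ± 0.508 FPKM. Both siRNAs called 2263 genes in the same direction, 1296 higher and 967 lower, or 1942 with replicates 1 and 2 alone, and 949 in opposite directions. Independent lists of these sizes would share 758.8 higher and 572.1 lower genes, with 1318 in opposite directions. Simulated unchanged groups, which yield few calls, shared at most 1. The same sign was found for 59.5% of all genes tested, against 66.7% simulated. Across genes r was 0.341 against 0.492 simulated, and the covariance was 0.0428 against 0.0107 simulated, a difference of 0.0321. The 3 control libraries were not split between the siRNAs, so part of the excess may come from the shared controls. In the authors' deposited table for siRNA2, 3329 genes had an adjusted p under the same threshold, and 3192 of them passed here, 3192 in the same direction. No deposited table for LINC00673 siRNA1 was used here.

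The knockdowns were then compared across the lines by the calls over both siRNAs, among the 11810 genes tested in both. Such a call is of the mean of the siRNAs, so a gene moved by 1 siRNA alone can count as shared. OSTM1 counted as lower in both lines (log2 changes -0.50 in Aspc1 and -1.04 in Panc1), though in Aspc1 it stayed near the control level with siRNA2. SLC36A1, a lysosomal amino acid transporter, rose in both lines with log2 changes of 0.72 in Aspc1 and 0.73 in Panc1, TNFRSF11B, the decoy receptor osteoprotegerin, with 0.68 and 0.74, and PDIA4, a protein disulfide isomerase, with 0.60 and 0.64. CLDN1 and MET, at the head of the rises in Panc1, also rose in Aspc1, by log2 changes of 0.57 and 0.51. C4orf34 had log2 changes of -0.60 and -0.58. In all, 384 genes rose in both lines where 255.8 would be shared by independent lists, with an odds ratio of 1.92 (95% interval 1.68 to 2.20, two-sided Fisher's exact test, adjusted p = 6.12e-20 over 4 tests). For genes lower in both lines the count was 269 against 238.6, with an odds ratio of 1.19 (1.03 to 1.38, Fisher's exact test, adjusted p = 0.0398). This call ended with pseudocount 0.1, a mean FPKM of at least 1 and quantile scaling (adjusted p = 0.0831, 0.105 and 0.111). It also ended with the robust fit, the replicate block and replicate 3 as a batch term (adjusted p = 0.0610, 0.0718 and 0.1002). It held with no filter on level (odds ratio 1.99, adjusted p = 3.49e-13) and median-of-ratios scaling (adjusted p = 0.0242). Without Aspc1 control replicates 1 and 2 its adjusted p was 0.549 and 0.380, without FAM83H-AS1 siRNA2 replicates 1 and 2 it was 0.525 and 0.707, and without Panc1 control replicate 3 and LINC00673 siRNA2 replicate 1 it was 0.0511 and 0.0517. Genes that rose in Aspc1 and fell in Panc1 numbered 220 against 246.4 (Fisher's exact test, adjusted p = 0.0621), and the reverse 257 against 247.8 (adjusted p = 0.490). With Panc1 replicates 1 and 2 alone the odds ratios were 2.06 for genes higher in both and 1.197 for genes lower in both (adjusted p = 0.0399). Target and cell line cannot be told apart here, since each target was lowered in a single line, and genes are not independent. Each line was set against its own control siRNA libraries, so a change made by a control siRNA could also be shared and cannot be told apart.

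The control libraries show how far the lines differ at baseline. The labels do not say that the lines were processed together, so the values are described and the line and any batch cannot be told apart. CDH17, an intestinal cadherin, was at 1065 ± 11.9 FPKM in Aspc1 (n = 2) and 0.469 ± 0.120 in Panc1 (n = 3), LGALS4 at 695.9 ± 33.9 and 0.498 ± 0.244, and EPCAM at 895 ± 11.6 and 11.9 ± 0.286. CEACAM6 was at 603 ± 3.10 FPKM in Aspc1 and listed at 0 in Panc1, and CCL2, a monocyte chemokine, was at 546 ± 22.2 in Panc1 and listed at 0 in Aspc1. LDHB, a lactate dehydrogenase subunit, was at 0.110 ± 0.0990 in Aspc1 and 484 ± 10.1 in Panc1, and CTGF at 3.71 ± 0.188 and 74.3 ± 4.41. Over 13844 genes tested, 11618 differed, 6063 higher and 5555 lower in Panc1. Of 17 mucin and gastric or ductal marker genes 0 were higher and 16 lower in Panc1 (0 and 17 adjusted over the list alone, mean log2 difference -3.81, adjusted p = 8.87e-06, adjusted p = 0.517 with an estimated correlation). Of 18 YAP and TEAD targets 15 were higher and 2 lower in Panc1 (15 and 2 adjusted over the list alone, adjusted p = 0.00377, adjusted p = 0.517 with an estimated correlation).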

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

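The tests of a scaling factor, of the degree of knockdown, of insulin against the knockdown and the search of all genes for islet transcripts were chosen only after the results were seen. So were the fits of Panc1 replicates 1 and 2 alone.

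The siRNAs against one target differed by a direct test, in 3109 genes and 10 gene lists in Aspc1 and in 7829 genes and 9 gene lists in Panc1, of which 0 and 0 lists held with an estimated correlation. In Aspc1 the gene count was 779 and 1173 without siRNA2 replicates 1 and 2 and 1873 without siRNA1 replicate 1. Of the genes called with both siRNAs, 104 of 754 in Aspc1 and 949 of 3212 in Panc1 went in opposite directions, against 168.3 and 1318 for independent lists of these sizes. The level of LINC00673 was itself higher with siRNA2 than with siRNA1 by a log2 difference of 1.31.

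For this difference between siRNAs, the first pattern, 1 scaling factor per library is argued against as the whole cause. Such a factor would move all genes one way, while 49.6% (95% Clopper-Pearson interval 47.8 to 51.4) and 47.3% (46.2 to 48.5) of the differing genes went in the less common direction. FPKM values are already scaled per library, so an even split was likely beforehand and this share alone decides little. With median-of-ratios scaling 3113 genes in Aspc1 and 7831 in Panc1 still differed. A bias that depends on level is not covered by these values. A weaker copy of one response would send few genes opposite ways, while 13.8% (Clopper-Pearson interval 11.4 to 16.5) and 29.5% (28 to 31.2) did so. In Aspc1 there was little difference in degree to test. FAM83H-AS1 was left at 40.6% of control with siRNA1 and 35.9% with siRNA2, and the libraries of these groups overlapped. Seed-matched silencing through 3' UTRs may account for part of the difference, as a hypothesis, and only genes that fell were searched for it. For FAM83H-AS1 siRNA1 and siRNA2 the top heptamer was in 36.0% and 25.4% of fallen genes of held-out chromosomes, against 17.9% and 12.4% of the others. For LINC00673 siRNA1 and siRNA2 it was in 23.5% and 28.4%, against 9.55% and 11.9%. Most fallen genes thus held no top heptamer. The top heptamers had odds ratios among fallen genes of held-out chromosomes of 3.14 (95% interval 2.41 to 4.10) and 2.66 (2.15 to 3.28) for FAM83H-AS1 siRNA1 and siRNA2, and 3.06 (2.57 to 3.63) and 3.58 (2.94 to 4.35) for LINC00673 siRNA1 and siRNA2, against 0.986, 0.968, 1.05 and 1.19 (the last with an interval of 1.003 to 1.42) among genes that fell with the other siRNA. The siRNA sequences are not given in the sources used here, so no heptamer could be set against a seed, the heptamers ranked next overlapped the top one for each siRNA except FAM83H-AS1 siRNA1, and effects of the target RNA stay open.

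The second pattern is the fall of replication, mitosis and DNA repair genes with both LINC00673 siRNAs, a median log2 change of -0.32 over 107 members. With an estimated correlation 2 lists passed with siRNA1 taken singly, so not all 3 of these lists held with that siRNA. Direct silencing through a top heptamer in each member's own 3' UTR is argued against as the whole cause. The 93 members with neither heptamer had a median of -0.31 (bootstrap 95% interval -0.34 to -0.26, with genes taken as independent). The 14 members with a heptamer had a median of -0.41. Only the top heptamer of each siRNA was searched, so other seed matches stay open. A fall of members that follows from a match in another gene, in or outside the lists, was not tested and stays open too. Loss of reads at low level is argued against, because the 53 members above the median FPKM had a median of -0.30 (-0.34 to -0.23). Of the 84 splits of the 9 libraries, 1 (the real split, mean -0.33) gave a mean as large in size. The largest other size, 0.23, set the siRNA1 libraries against the rest. The 3 lists were taken up because they fell in the real split, which favours that split, so this rank cannot exclude chance. An effect of losing LINC00673 and other effects that both siRNAs share stay open, and either may contribute.

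The third pattern is transcripts of INS, GCG, CHGA, TTR and SST in all 6 Aspc1 libraries and, with PPY, at higher levels in the replicate 3 library of each Panc1 group than in the other 6, while CHGB and SCG2 of the same list overlapped. An effect of the knockdown is argued against by the levels of INS, which was at 8.65 and 21.7 FPKM in the Aspc1 controls, at 4.52 in Panc1 control replicate 3 and listed at 0 in Panc1 replicates 1 and 2 of both siRNAs, and each siRNA group overlapped its controls (smallest adjusted p of INS over the 4 single-siRNA comparisons 0.308). RNA or reads from islet cells is a candidate source, and its test, written before the values were seen, came out against it, with a lowest replicate 3 sum of 15 further islet genes at 0.543 of the highest sum among the other 6 Panc1 libraries. That test is judged uninformative, a judgement made after seeing the values, because PCSK1N and RBP4 made up 88.4% of the sums in the other libraries. A later search of all genes for those at 0.3 FPKM or more in every replicate 3 library and over 4 times the other libraries found 6, and 6 of these were on the fixed islet list of 9 (CHGA, GCG, INS, PPY, SST and TTR), while the same search in reverse found 1 gene, but its limits were set after these genes had been seen, so it restates the pattern and a source in islet RNA stays open.

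The fit with both siRNAs as 1 group called 1478 genes in Panc1. Of the 84 splits of the 9 Panc1 libraries into 6 and 3, 2 gave as many, the real split included. The highest other, 6706, set the siRNA1 libraries against the rest, and setting the siRNA2 libraries against the rest gave 1445. The median of the other splits was 0. The highest counts came from splits along the 3 groups, so the test shows that libraries differ by group. It cannot set control against both siRNAs apart from either siRNA against the rest. For the number of gene lists, 55 of 84 splits gave as many as the real 6 in this fit (highest other 15), so chance cannot be excluded for that number. For siRNA1 against control, siRNA2 against control and siRNA2 against siRNA1, 1 of 10 splits each gave as many genes as the real 7622, 3979 and 7933, with 3, 4 and 2 as the highest other, and 10 splits are too few for a share under 0.05.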

How the results depend on the processing

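The fits of Panc1 replicates 1 and 2 alone and with replicate 3 as a batch term were chosen only after the results were seen. Where a value below moved, the cause was not tested, except that the fits of 1 siRNA with its control and those without a library use fewer samples, a fit that pools both siRNAs as 1 group counts differences between them as spread, and a minimum log2 change of 1 keeps fewer genes. Without filter the Aspc1 counts were 1482 over both siRNAs, 783 with siRNA1 and 378 shared. With only the groups compared they were 114 (siRNAs pooled), 704 and 378, and 1478 over both siRNAs (pooled) in Panc1. Replicate numbers as a whole do not pair the samples, although the 3 Panc1 replicate 3 libraries gave r of 0.195, 0.123 and 0.164 with each other (r of deviations -0.0506 to 0.00695 for the same number in Aspc1, -0.0407 to 0.195 in Panc1, where different numbers gave -0.218 to 0.208 and not every library correlated best with its own number), and with the replicate block the Aspc1 counts were 1578 over both siRNAs, 801 with siRNA1, 2558 with siRNA2, 2317 between siRNAs and 379 shared, and the Panc1 counts 6819, 8295, 4931 and 8191. With the block the Panc1 NF-kB list was not called (adjusted p = 0.0593), nor in Aspc1 were TOP1MT and RHPN1 (adjusted p = 0.0628 and 0.0840), FAM83H with siRNA2 (adjusted p = 0.0838) or LINC00673 between siRNAs (adjusted p = 0.0638). In Panc1 the list of unfolded protein response and ATF4 target genes, not called over all libraries, was called with the block, the batch term, replicates 1 and 2 alone and no filter (adjusted p = 0.0382, 0.0392, 0.0255 and 0.0402). So were hypoxia with replicates 1 and 2 alone and no filter (0.0391 and 0.0487), matrix proteases with replicates 1 and 2 alone (0.0439), oxidative phosphorylation with no filter and quantile scaling (0.0302 and 0.0379) and without any of 4 libraries (0.0356 to 0.0498), and TGF-beta targets without control replicate 2 (0.0441). In Aspc1 mitosis was called with no filter and without control replicate 1 (0.0247 and 0.00513), and epithelial junctions without control replicate 1 (0.0206). With a log2 change of at least 1 the Aspc1 counts were 9, 13, 35, 36 and 1, the Panc1 counts 60, 369, 85, 413 and 20, and 4730 between the lines. With an estimated correlation 0 lists held in Aspc1 and 3 in Panc1. The odds ratio of genes lower in both lines lost its call in 6 of 9 settings, being 1.17 with pseudocount 0.1, 1.14 with mean FPKM of at least 1, 1.14 with quantile scaling, 1.17 with the robust fit, 1.19 with the replicate block and 1.16 with the batch term. It stayed called with no filter, median-of-ratios scaling and replicates 1 and 2 alone. Leaving out 1 library, where a group of 1 is assumed to vary like the others, gave 744 to 2032 over both siRNAs in Aspc1, 384 to 636 with siRNA1, 947 to 3474 with siRNA2, 779 to 2727 between siRNAs, 165 to 356 shared, and odds ratios of 1.04 to 1.24. In Panc1 it gave 5229 to 6194 over both siRNAs and 1707 to 2133 shared, and the knockdowns stayed between -0.81 and -0.74 (FAM83H-AS1) and -2.98 and -2.87 (LINC00673). With pseudocount 0.1 they were -1.29 and -3.23, since a smaller pseudocount shrinks low levels less. Nuclear and small noncoding RNA in Aspc1 ranged from -0.27 to 0.28, against a mean of 0.0046 and a median of -0.07 over all libraries, and was called lower without control replicate 2 (-0.27, adjusted p = 0.0319) and siRNA2 replicate 2 (-0.19, adjusted p = 0.00977). Of values of named genes, 509 of 636 in Aspc1 and 998 of 999 in Panc1 kept their side of the threshold without 1 library, and 691 of 740 and 994 of 995 under the other settings. Of list values, 323 of 342 and 512 of 531 did so without 1 library. Relative depth was 0.786 to 1.23 over the libraries, and the limit that depth sets on genes of low level is unknown.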

Other observations

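The comparison of cholesterol synthesis genes over the 4 siRNAs was chosen only after the results were seen. The siRNA2 against siRNA1 differences held further gene groups. NRF2 targets, genes of the oxidative stress response, were higher with siRNA2 in Aspc1, with 14 higher and 1 lower of 22 (15 and 1 adjusted over the list alone, mean log2 difference 0.30, adjusted p = 6.87e-06, adjusted p = 0.392 with an estimated correlation). In Panc1 10 were higher and 1 lower of 18 (10 and 1 adjusted over the list alone, 0.22, adjusted p = 0.0194, adjusted p = 0.369 with an estimated correlation). MHC class I antigen presentation genes were lower with siRNA2 in Aspc1, 0 higher and 8 lower of 15 (0 and 9 adjusted over the list alone, -0.30, adjusted p = 9.26e-05, adjusted p = 0.521 with an estimated correlation). In Panc1 NF-kB and cytokine genes were lower with siRNA2, 2 higher and 16 lower of 19 (2 and 16 adjusted over the list alone, -0.56, adjusted p = 0.000381, adjusted p = 0.369 with an estimated correlation). Hypoxia and glycolysis genes were lower too, 4 higher and 19 lower of 30 (4 and 19 adjusted over the list alone, -0.29, adjusted p = 0.00243, adjusted p = 0.369 with an estimated correlation). ERK pathway output genes had 2 higher and 15 lower of 26 (2 and 16 adjusted over the list alone, -0.32, adjusted p = 0.00174, adjusted p = 0.369 with an estimated correlation).

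Of 23 cholesterol synthesis genes tested in both lines, 15 were higher with all 4 siRNAs and 4 were called with all 4. Unchanged groups set against shared simulated controls gave 2.48 such higher genes on average and at most 7 in 1000 simulations. Genes were drawn independently, which genes of a list are not, and the real control libraries were not held fixed. Of all 11810 genes tested in both lines, 1254 (10.6%) were higher with all 4 and 85 were called higher with all 4. The 4 called cholesterol genes were ACAT2 (log2 changes 0.26 and 0.52 with FAM83H-AS1 siRNA1 and siRNA2, 0.68 and 0.32 with LINC00673 siRNA1 and siRNA2), INSIG1 (0.24, 0.64, 0.78 and 0.67), MSMO1 (0.26, 0.75, 1.19 and 0.76) and SQLE (0.44, 0.55, 0.88 and 0.55). No untransfected library was used here.

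At baseline, mitosis genes were higher in Panc1 control libraries than in Aspc1 control libraries, 33 higher and 3 lower of 38 (33 and 3 adjusted over the list alone, mean log2 difference 0.83, adjusted p = 1.37e-05, adjusted p = 0.517 with an estimated correlation). Glucagon (GCG) was at 3.89 and 9.92 FPKM in the Aspc1 controls, 4.03 and 7.78 with FAM83H-AS1 siRNA1, and 34.6 and 5.25 with siRNA2. INS over GCG was between 1.73 and 2.88 in the 6 Aspc1 libraries and between 0.83 and 1.07 in the 3 Panc1 replicate 3 libraries. None of 11 acinar genes was above 0.522 FPKM in any library.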
